A study of Homo sapiens with 16 samples.

How the data were processed

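K562 cells with libraries of short or long inserts in an episomal or a lentiviral vector were measured by TSS-MPRA and by DNA sequencing, with 2 replicates of each of the 8 groups. Per the labels, capped RNA was enriched by removing phosphates from uncapped RNA, the cap was removed, adapters were ligated to the 5 prime ends, and the cDNA was sequenced from both ends. The submitters' notes name STAR 2.7.9a and the genome build hg38; the steps from reads to the deposited tables are not stated.

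The deposited tables give, for each barcoded insert, the count of RNA reads and the count of DNA reads, and for each position of the insert the fraction of the RNA reads that start there, per the file headers and the values. The authors' table names speak of TPM, but the counts are whole and their totals differ between samples, so no normalization is in them. The fraction of each insert sums to 1 or 0. Multiplied by the RNA count, between 93.7% and 99.97% of the nonzero fractions in the main tables lay within 0.05 of a whole number, the lowest in LentiLong replicate 2 (91.1% in its core table, a second deposited table of the long libraries with reads in a middle window of positions). Products were rounded to whole reads.

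Each table stacks 4 blocks of values without a sample column. The blocks were assigned to samples by the order of the sample names that each table carries, on which the replicate numbers rest alone. The vector blocks could be told from the others because the other 2 blocks had no DNA reads and were identical in the tables of both vectors. These 12 other blocks, named as csRNA, were not used here, since no sample of the series carries that label. The plan written before the data were examined foresaw TPM or counts and chose the test by unit, but it did not foresee DNA counts beside the RNA counts, so that every ratio of RNA to DNA was added later.

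Insert names carry a region on hg38. Position 128 of the short and 203 of the long inserts was the middle of the named region: at this offset 55.7% to 65.2% of starts fell on a pyrimidine followed by a purine in the reference, against 26.1% or less at the next best offset within 400 bp. An insert took the name of a gene when a GENCODE v44 transcript start lay within 500 bp of that middle, and motif inserts took the name in the table. Coordinates are those of the whole insert.

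RNA counts were summed over the barcodes of an insert, 4 in short and 2 in long libraries, with a median of 1856 to 14470 RNA reads per barcode across samples. The vectors, and the short and long inserts within a vector, were compared with the edgeR 4.0.16 quasi-likelihood test (TMM scaling, inserts with a mean of at least 10 counts, Benjamini-Hochberg adjusted p under 0.05) in R 4.3.3. RNA per DNA was tested as the interaction of molecule and group over RNA and DNA counts in edgeR. Chi-square over degrees of freedom between replicates ran from 15.6 to 1628, so replicates differed by more than sampling. Gene lists were tested with camera from limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, for lists of at least 3 inserts. The lists were ribosomal protein genes, proteasome, respiratory chain, histones, splicing and snRNA, erythroid genes, immediate early and stress genes, interferon response, cell cycle, translation factors, chaperonin, and genes of other cell types.

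Changed inserts were compared with their controls by limma on log2 of (RNA + 1) over (DNA + 1) per barcode, averaged over both replicates, for barcodes with at least 20 DNA reads, inserts with at least 2 such barcodes, and pairs with a mean of at least 10 RNA reads per barcode in either insert. The difference between the vectors was tested by limma on the difference of the same barcode between vectors. Start profiles were compared by the earth mover distance in bp between cumulative profiles of inserts with at least 50 reads in each sample, and for changed inserts over the 35 splits of 8 barcodes.

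Promoter elements were sought as fixed consensus sequences in the hg38 sequence of located inserts, and elements with at least 5 inserts with and without were compared by two-sided permutation tests with 100000 draws across inserts, on log2 RNA per DNA (at least 20 DNA reads per insert) and on the vector differences. Camera was not run on elements. Intervals come from 2000 bootstrap draws at 95%. Programs were python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9 and samtools 1.23.1, with DESeq2 1.42.0 as an alternative.

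The inserts named for the vector comparison follow a rule fixed before the data were examined: per library the 10 largest differences in each direction among inserts past the threshold, with both replicates of one vector above both of the other and a mean of at least 50 counts, 1 per gene; for profiles the 5 most and the 5 least dissimilar inserts whose replicates differ by under 5 bp; and every member of a list. Of the inserts that this rule selects 1 is not reported here. Names among control promoters, changed inserts and lengths, the comparison of changed inserts with controls, of genome places, of GC content and of short with long profiles were chosen after the data were seen.

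On simulated counts with known changes the edgeR test of short inserts called 100% of 1.5-fold, 2-fold and 4-fold changes and 1.67% of 299 unchanged inserts. That of long inserts called 82.4%, 100% and 100%, and 0% of 149. In the simulation 200 of 499 short and 100 of 249 long inserts were changed, up and down in turn, with a common dispersion. A larger share of inserts differed in the data, so these rates need not hold there. The limma test of pairs called 90.7% (episomal) and 86.4% (lentiviral) of changes of 1 on the log2 scale, all of 2, and 0% and 2.90% of unchanged pairs.

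The alternatives tried were other scalings (RLE, library totals, centring on the median, quantile normalization, DESeq2), other count filters, no trend of the spread, the replicate number as a block, leaving out each replicate, the core table, RNA per DNA, other pseudocounts for correlations and pairs, other minimum reads and distances for profiles, thinning of profiles to 50 reads, a 100-bp window for elements, and regression on GC content.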

Results

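K562, a human erythroleukaemia cell line that expresses globin genes, carried libraries of short DNA inserts whose transcription start sites were read by TSS-MPRA. TSS-MPRA is a massively parallel reporter assay in which the 5 prime ends of capped RNA are sequenced, so that each read gives the insert it came from and the base at which transcription started. The labels name 4 sets of libraries: episomal plasmids (Epi) and integrated lentiviral vectors (Lenti), each with short inserts (200 positions) or long inserts (350 positions). Each set had 2 TSS-MPRA samples and 2 DNA sequencing samples of the same libraries, 16 samples in all. According to the series title the assay was used to study which sequences determine where transcription starts.

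The short libraries held 499 inserts, each with 4 barcodes. Of these, 250 were genomic start sites drawn at random, 91 carried alleles at genome-wide association (GWAS) sites, 78 were named promoters and enhancers with single motifs mutated, and 40 each belonged to sets in which a splice donor had been added or mutated. The long libraries held the 250 random sites with 2 barcodes each. Among these random sites 101 lay within 500 bp of an annotated transcript start on the same strand, 53 of an opposite-strand start, and 96 of neither. RNA reads numbered 21571370 and 19020540 in the EpiShort replicates, 11140433 and 11741702 in LentiShort, 26720416 and 25766991 in EpiLong, and 14409521 and 16877640 in LentiLong. DNA reads numbered 15286382 and 1698930 in EpiShort, 8614823 and 9989471 in LentiShort, 8525746 and 8118349 in EpiLong, and 6104945 and 6929169 in LentiLong. Reads are PCR products without molecular identifiers, so floors cover counting error only. The bootstrap intervals cover the spread across the inserts or pairs that were resampled, not that between libraries.

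RNA reads per insert correlated closely between the replicates of a group. They were not divided by DNA reads, so that unequal shares of the inserts in a library also enter the correlations. Across inserts, which are not independent replicates, the Spearman correlation of log2 RNA reads between replicates was 0.999 in EpiShort (494 inserts), 0.999 in LentiShort (498), 0.994 in EpiLong (249) and 0.999 in LentiLong (247). The Pearson correlations were 0.998, 0.998, 0.994 and 0.995.

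The first question was how the vector changes the output of an insert. Among short inserts the promoters of the erythroid genes gave more RNA from the lentiviral than from the episomal vector. The difference (log2 ± SE, n = 2 replicates per vector, edgeR) was 3.86 ± 0.09 for HBZ, the embryonic alpha-like globin, 1.69 ± 0.07 for HBE1, the embryonic beta-like globin, 1.14 ± 0.08 for HBG2, a fetal globin, and 1.07 ± 0.07 for GATA1, the transcription factor of red cell development. Under the scalings tried HBZ ran from 3.62 to 4.54, HBE1 from 1.30 to 2.37, HBG2 from 0.60 to 1.82 and GATA1 from 0.57 to 1.75. The promoter of SF3B1, a splicing factor, gave less RNA from the lentiviral vector (-2.54 ± 0.06), as did the NPRL3 promoter (-1.88 ± 0.07) and its antisense insert (-2.06 ± 0.06). The ACTB promoter moved little (0.24 ± 0.06, between 0.02 and 0.99 under the scalings tried), and the JUN promoter gave 0.00 ± 0.07, which did not pass the test. After division by DNA reads the erythroid promoters remained higher in the lentiviral vector, at 2.58 ± 0.16 for HBZ, 3.15 ± 0.16 for HBE1, 1.53 ± 0.17 for HBG2 and 0.93 ± 0.16 for GATA1, and SF3B1 remained lower, at -2.10 ± 0.11.

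Of 499 short inserts tested, 444 differed between the vectors at an adjusted p under 0.05, 225 higher and 219 lower in the lentiviral vector, and 135 and 118 of these by over 2-fold. Scaled by library totals alone, 448 differed, 314 higher and 134 lower, since the median of all inserts then moved to 0.72 from 0.04. The RNA-per-DNA fit called 404, 189 higher and 215 lower. DNA reads alone also differed between the vectors for 405 of the 499 inserts. The p-values measure the spread between these samples, which may be technical, and each vector and insert length was a set of libraries of its own, so that vector and library preparation cannot be told apart.

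Among the 10 short inserts with the largest lentiviral excess, 3 lay at an annotated transcript start on their strand. The allele insert near IL18RAP, a receptor subunit for interleukin 18 (chromosome 2, 102418525 to 102418724, intergenic), an intronic site on chromosome 5 (54325636 to 54325835, minus strand), a site opposite ADNP (chromosome 20, 50931590 to 50931789) and the OPRL1 UTR allele insert (chromosome 20, 64079982 to 64080181) gave 0 episomal RNA reads. Against a floor of 3 reads per library they were at least 287-fold, 230-fold, 205-fold and 38.7-fold higher in the lentiviral vector, the lowest bounds over TMM, RLE, library totals and median centring. However, these inserts had 0 to 3 episomal DNA reads in each replicate. The PPP1R16B intron (chromosome 20, 38854943 to 38855142) was higher by 9.29 ± 0.24, but by 0.98 ± 0.71 per DNA, which did not pass the test. A non-coding exon on chromosome 5 (134438035 to 134438234) was higher by 7.05 ± 0.17 in RNA and lower per DNA (-0.83 ± 0.36). The donor-added insert in GABPB1 (chromosome 15, 50353848 to 50354047) was higher by 4.58 ± 0.08, an AMMECR1 intron (chromosome X, 110373415 to 110373614) by 4.56 ± 0.08, the ADD2 promoter (chromosome 2, 70717636 to 70717835) by 4.45 ± 0.08 and an FPR1 intron (chromosome 19, 51785086 to 51785285) by 4.43 ± 0.08. These last inserts were also higher per DNA, by 4.62, 1.73, 2.57 and 3.94. The adjusted p-values of the RNA differences ran from 8.02e-14 to 7.16e-06 (edgeR).

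Among the 10 with the largest episomal excess, 7 lay at an annotated transcript start on their strand. ZSCAN29, a zinc finger gene (chromosome 15, 43370951 to 43371150), was lower in the lentiviral vector by -3.93 ± 0.10 and by -4.31 ± 0.14 per DNA. GPN1 (chromosome 2, 27628923 to 27629122) differed by -3.43 ± 0.06, WDR74, a ribosome biogenesis gene (chromosome 11, 62839501 to 62839700), by -3.35 ± 0.05, CDC26, an anaphase-promoting complex subunit (chromosome 9, 113275512 to 113275711), by -3.17 ± 0.07, BCL2L1, an inhibitor of apoptosis (chromosome 20, 31723888 to 31724087), by -3.14 ± 0.08 and ZDHHC4 (chromosome 7, 6577361 to 6577560) by -3.12 ± 0.07. ENSG00000289569 on chromosome 13 differed by -3.80 ± 0.15 and an intergenic site on chromosome 7 (96358277 to 96358476) by -3.15 ± 0.06. Among the mutated inserts, the Stat3 mutant of the NPRL3-enh1neg enhancer differed by -3.84 ± 0.16 and the TATA box mutant of the HBE1-HS5neg element by -3.22 ± 0.09. Under the scalings tried the former lay between -7.06 and -3.16 and the latter between -3.96 and -2.53. The mutant of HBE1-HS5neg differed by -0.58 ± 0.26 per DNA. The adjusted p-values of these inserts ran from 8.02e-14 to 7.92e-11 (edgeR), and both lentiviral replicates lay below both episomal ones.

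Among long inserts 201 of 249 differed, 99 higher and 102 lower in the lentiviral vector, and 61 and 57 of these by over 2-fold. The long insert of SNRK, a kinase gene (chromosome 3, 43286424 to 43286773), was higher in the lentiviral vector by 8.18 ± 0.43 and that of ANKRD31 (chromosome 5, 75236731 to 75237080) by 7.19 ± 0.52, but neither passed the test per DNA, at 0.33 ± 0.68 and 0.56 ± 0.65. Sites opposite NBAS (4.47 ± 0.17) and VWDE (3.90 ± 0.18), and sites in introns on chromosomes 5 (from 54325561, 4.92 ± 0.32), 7 (from 131072099, 4.59 ± 0.11) and 6 (from 146887273, 4.26 ± 0.12) were higher in RNA and per DNA. The PPP1R16B intron was higher by 4.13 ± 0.11 and by 1.15 ± 0.14 per DNA, and an intergenic site on chromosome 6 (from 35731814) was higher by 4.26 ± 0.13 and lower per DNA (-0.64 ± 0.12).

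Among the 10 long inserts with the largest lentiviral excess 2 lay at an annotated transcript start on their strand, and among the 10 with the largest episomal excess 9 did. The latter were ANPEP, an aminopeptidase (-3.76 ± 0.74), PCGF5, a Polycomb ring finger gene (-3.53 ± 0.48), PSMG4, a proteasome assembly chaperone (-3.38 ± 0.21), GORASP1, a Golgi stacking protein (-3.12 ± 0.16), WDR74 (-2.96 ± 0.09), BLCAP (-2.94 ± 0.10), ZXDC (-2.72 ± 0.40), TAF9B (-2.54 ± 0.19) and ZSCAN29 (-2.29 ± 0.39). Their adjusted p-values ran up to 0.00373 (edgeR). ANPEP had 73 and 12 lentiviral reads, and leaving out lentiviral replicate 1 or 2 moved its difference to -5.70 or -2.94. All of these were also lower per DNA, between -5.87 for ZXDC and -1.30 for WDR74. The site opposite C17orf58 had 0 lentiviral RNA reads, which made it at least 30.2-fold lower by the same bounds, but it had no DNA reads in either vector. Per DNA 211 of 248 long inserts differed, 99 higher and 112 lower. The median of all long inserts moved to -0.11 under library totals, -0.15 after centring each column on its median and -0.16 after quantile normalization, from 0.06, and that of the short inserts to -0.18 after centring.

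The lists of genes fixed in advance were mostly thinly covered. All 4 erythroid inserts, the promoters of GATA1, HBE1, HBG2 and HBZ, were higher in the lentiviral vector, 4 of them past the threshold adjusted over the list alone, under each scaling tried, with a median of 1.41 and of 2.06 per DNA. As a set they ranked above the other inserts by camera with an adjusted p of 0.0330, and of 0.0119 per DNA, but the call was lost with an estimated correlation (adjusted p = 0.324, and 0.0974 per DNA). The study chose these promoters for its library. Motif inserts were not located, so how far GC content accounts for their differences was not examined. Of the HBE1-HS control elements, HBE1-HS1neg and HBE1-HS1pos were higher and HBE1-HS2pos and HBE1-HS5neg lower under each scaling tried. HBE1-HS2neg and the HBE1-HS3 and HBE1-HS4 elements took either sign. Of the ribosomal protein genes RPL37 was lower (-2.72 ± 0.08), while RPLP1 (-0.76 ± 0.05) and RPS26 (0.56 ± 0.24) passed the test but each took either sign under the scalings tried; 3 passed over the list alone, and camera gave an adjusted p of 0.204 (0.327 with an estimated correlation). Both splicing genes were lower, SF3B1 and SF3B3 (-1.08 ± 0.12), although SF3B3 was higher per DNA (1.01); the long SF3B3 insert gave -0.31 ± 0.17, which did not pass. NDUFC1, a respiratory chain subunit, was higher in long inserts (1.27 ± 0.10), and its short insert (0.25 ± 0.09) took either sign under the scalings tried. Neither immediate early gene, DUSP1 (-0.07) or JUN, passed. The proteasome, histone, interferon, cell cycle, translation factor and chaperonin lists and the list of genes of other cell types had 0 inserts.

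In the episomal vector, random sites at an annotated transcript start on the same strand gave more RNA per DNA than sites with no transcript start nearby. The medians differed by 1.36 on the log2 scale for short inserts (101 against 94, adjusted p = 0.00156, two-sided permutation test across inserts) and by 1.10 for long inserts (100 against 96, adjusted p = 0.00954). In the lentiviral vector the same difference was 0.41 (adjusted p = 0.394) and -0.24 (adjusted p = 0.541), neither past the threshold. The vector difference itself was lower at same-strand starts than at sites with none, by -0.79 for short inserts (adjusted p = 0.00319) and by -2.02 for long inserts (adjusted p = 9e-05, from the smallest p that the permutations can give, 1e-05). Sites opposite a transcript start also lay below sites with none, by -0.69 for short (adjusted p = 0.0144) and -1.77 for long inserts (adjusted p = 9e-05), and short ones were more active than sites with none in the episomal vector (1.18, adjusted p = 0.0112). No difference between same-strand and opposite sites passed the threshold in these tests. GC content, which went with the vector difference of RNA per DNA, was not regressed out here. How far it accounts for the differences by place was not tested.

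The vector difference followed base composition. Across located inserts, which are not independent replicates, the Spearman correlation of GC content with the lentiviral minus episomal RNA per DNA was -0.517 for 329 short inserts and -0.799 for 247 long inserts. GC-rich inserts made up more of the lentiviral DNA libraries (0.556 short, 0.740 long) and somewhat less of the lentiviral RNA (-0.126 short, -0.368 long). Inserts with a GC box, the site of SP and KLF factors, had a lower vector difference of RNA per DNA, by -0.64 in short and -2.25 in long inserts, and those with an ETS site by -1.0 and -1.08. Short inserts with a YY1 site were lower by -1.74, and short inserts with a CCAAT box, the site of NFY, were higher by 1.11, with a GATA site by 1.14 and with a polypyrimidine initiator by 0.82. In all, 6 of 13 elements passed for short inserts and 5 of 11 for long inserts (permutation tests across inserts), and after GC content was regressed out 1 and 0 did, the CCAAT box in short inserts (0.82, adjusted p = 0.00091) and none in long inserts, where 1 had an unadjusted p under 0.05.

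**Figure D1:**
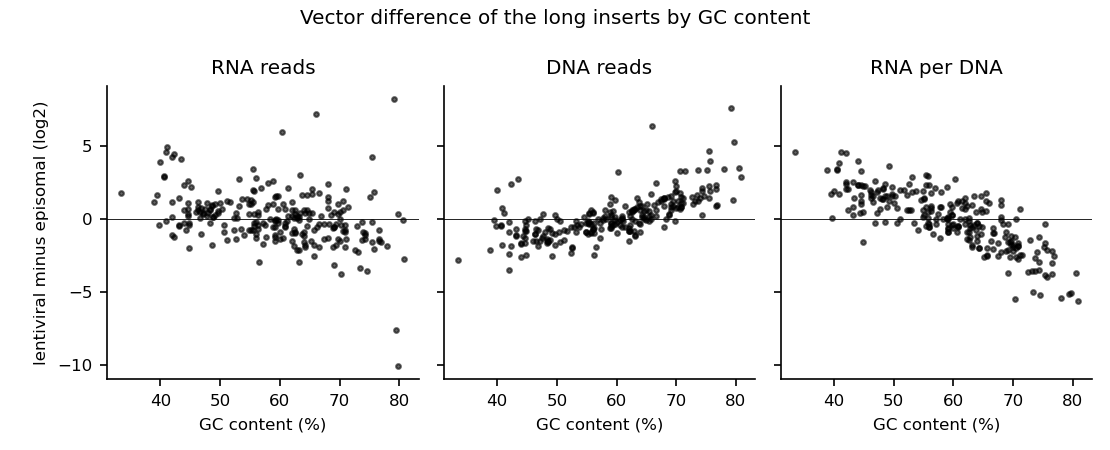
Log2 lentiviral minus episomal difference of RNA, DNA and RNA per DNA (vertical axes) against the GC percent of each located long insert (horizontal axes), each point an insert, mean of 2 replicates. The DNA difference rises with GC percent (Spearman 0.740 across inserts) and the RNA-per-DNA difference falls (-0.799).

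For RNA itself, short inserts with a CCAAT box differed by 0.66 (77 with and 258 without, adjusted p = 0.0408) and those with an ETS site by -1.05 (39 and 296, adjusted p = 0.00767), 2 of 13 elements; 4 of 11 passed in long inserts, the GC box (-0.77), the polypyrimidine initiator (0.70), the NRF1 site (-1.28) and the ETS site (-0.71). Within a vector, short inserts with an ETS site were more active episomally (1.95, adjusted p = 0.00052), 1 of 13 elements, and 0 of 13 passed in the lentiviral vector, where 3 had an unadjusted p under 0.05. For long inserts 0 of 11 passed episomally, with 0 at an unadjusted p under 0.05, and 4 of 11 in the lentiviral vector. After GC content was regressed out, 0 elements passed in each of these tests (1 to 3 had an unadjusted p under 0.05, or 0 for long inserts in the episomal vector), and the GC box turned in sign for long inserts (0.13 for RNA).

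The designed mutations asked which motifs an insert needs. Mutation of the NRF1 motif took most of the RNA per DNA from the antisense NPRL3 promoter, by -5.89 ± 0.33 in the episomal and -3.31 ± 0.28 in the lentiviral vector (log2 ± SE, up to 4 barcodes per insert, limma). AP-1 mutations, which remove the site of FOS and JUN factors, lowered the beta-globin locus control elements HBE1-HS2pos (-4.08 ± 0.18 and -1.07 ± 0.17), HBE1-HS4pos (-2.97 ± 0.29 and -0.72 ± 0.25) and HBE1-HS4neg (-2.23 ± 0.27 and -1.12 ± 0.32). NFY mutations lowered the globin promoter HBE1 (-0.96 ± 0.25 and -2.82 ± 0.20), HBE1-HS1neg (-0.66 ± 0.19 and -3.13 ± 0.20), HBZ (-1.19 ± 0.34 and -1.37 ± 0.21) and ACTB (-1.71 ± 0.29 and -1.79 ± 0.18). GATA1 motif mutations lowered the NPRL3 enhancers enh2pos (-2.11 ± 0.24 and -1.74 ± 0.25) and enh3pos (-1.96 ± 0.45 and -1.77 ± 0.37), which sit in the gene that houses the alpha-globin enhancers. Mutation of the E-box motif named Usf2 raised the NPRL3 promoter (2.80 ± 0.28 and 3.22 ± 0.35) and lowered HBE1-HS2neg (-1.96 ± 0.24 and -2.91 ± 0.28).

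Of the motif mutants 25 of 48 passed in the episomal vector, 4 raised and 21 lowered, and 30 of 51 in the lentiviral vector, 9 raised and 21 lowered. Among the 20 that passed in both, 18 had the same sign, and the TATA box and CDX4 mutants of ACTB did not. Where these ACTB mutations lie in the insert is not known here, so they may overlap and need not be separate cases. The effects of motif mutants differed between the vectors past the threshold for 18 of 48, in a test of the difference itself. The AP-1 effect at HBE1-HS2pos was weaker in the lentiviral vector by 3.01 ± 0.18, and the NFY effect at HBE1-HS1neg was stronger there (-2.46 ± 0.22). Mutating the TATA box of ACTB gave -1.32 ± 0.18 in the episomal and 0.63 ± 0.17 in the lentiviral vector, and mutating its CDX4 motif -1.44 ± 0.17 and 0.54 ± 0.19. The positive lentiviral signs rest on the division by DNA reads. The TATA box mutant had fewer lentiviral RNA reads than its control (56689 and 57446 against 67635 and 69091), as did the CDX4 mutant (a mean of 64937 against 68363). The TATA box mutant of HBZ lost more RNA per DNA in the lentiviral vector (-1.87 ± 0.20 against -0.77 ± 0.25, difference -1.10 ± 0.25). These p-values measure the spread among barcodes within the libraries, not between transfections, and mutants of a promoter share its control insert. Without division by DNA reads, which leaves unequal barcode shares in the values, 13 motif mutants passed in the episomal vector, 1 raised and 12 lowered, and 21 in the lentiviral vector, 3 raised and 18 lowered.

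**Figure D2:**
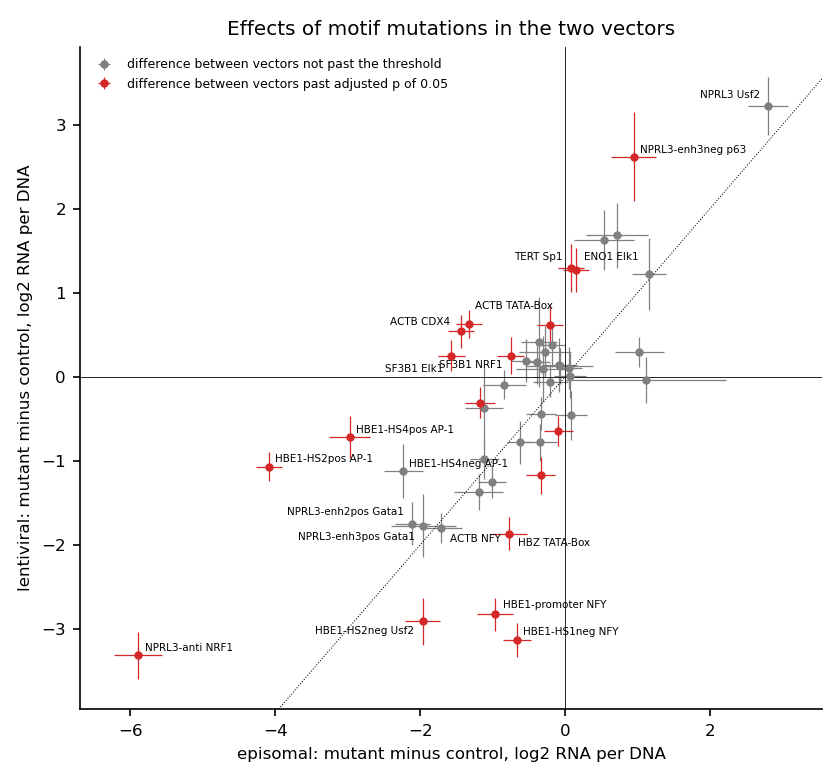
Log2 RNA per DNA of each motif mutant minus its control in the episomal (horizontal axis) and the lentiviral vector (vertical axis), with SE bars from limma over 2 to 4 barcodes per insert; the dotted line marks equal effects. Mutants in red differ between the vectors past the threshold, such as AP-1 of HBE1-HS2pos (-4.08 and -1.07) and TATA-Box of ACTB (-1.32 and 0.63).

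Several motif mutations also moved the start site. The control ACTB promoter, with a TATA box, started at position 128 with 85.6% of episomal and 87.9% of lentiviral reads. With its TATA box mutated this fell to 11.5% and 0.949%, and the most used start lay at position 101 in both vectors. The CDX4 mutant of ACTB did the same (2.42% and 0.595%, main start 101), while the NFY mutant, which lost RNA, kept 70.6% and 71.4% at position 128. The TATA box mutant of HBZ kept position 128 as its main start in the episomal vector, at a mean of 24.9% over barcodes against 61.7% in the control. In the lentiviral vector it moved to position 96, with a mean of 1.38% left at 128 against 63.6%. Elk1 mutants, which lose an ETS site, moved the main start from 128 to 81 at SF3B1 and from 128 to 101 at ENO1 in both vectors, and the YY1 mutant of HBE1-HS5neg moved from 128 to 142 in the episomal and 136 in the lentiviral vector. The positions of the replaced bases in these mutants are not known here. New starts within replaced bases therefore cannot be told from starts in unchanged sequence. In a comparison of the 35 splits of the 8 barcodes of a pair, the real split gave the most dissimilar start profiles for 24 of 45 motif mutants in the episomal and 32 of 46 in the lentiviral vector, where chance would give 1.29 and 1.31. For single-base alleles it did so in 10 of 42 and 11 of 43 pairs, where chance would give 1.2 and 1.23. The main start moved by over 5 bp in 9 of 45 episomal and 14 of 46 lentiviral motif mutants. For inserts with a single-base allele it was 9 of 42 and 10 of 43. The share for episomal motif mutants was thus near that of the alleles.

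**Figure D3:**
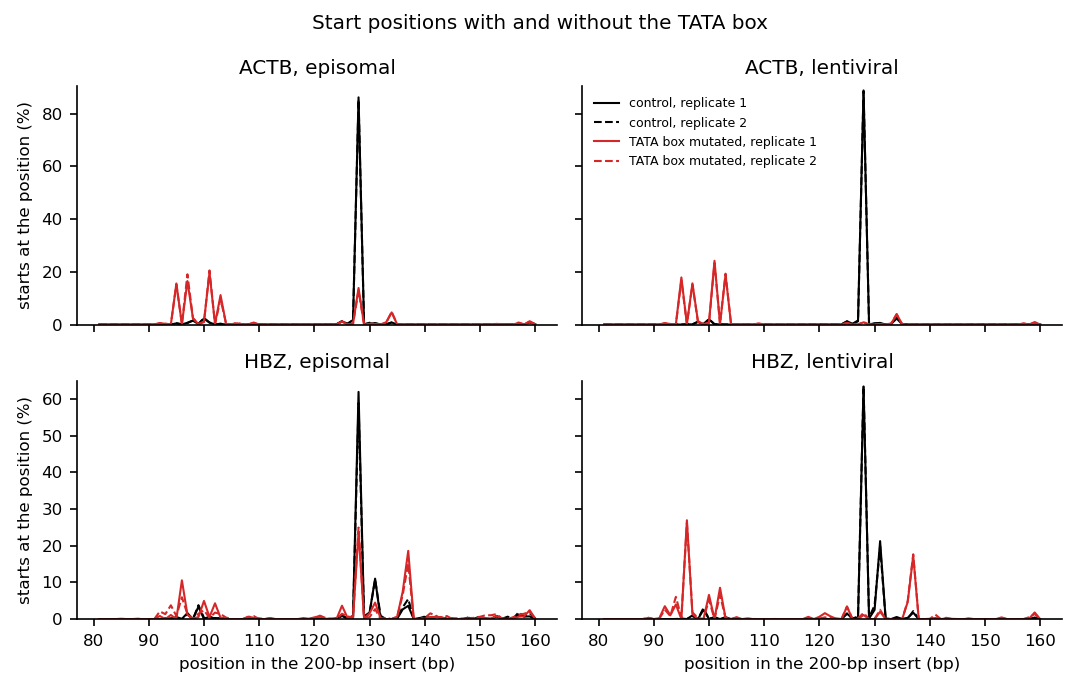
Percent of reads that start at each insert position (81 to 160) in the ACTB and HBZ promoters with an intact or mutated TATA box, in the episomal and lentiviral vectors, replicate 1 solid and replicate 2 dashed. Starts at position 128 of ACTB fall from 86.1% and 85.2% to 13.9% and 12.9% of episomal reads (replicates 1 and 2). Lentiviral reads there fall from 88.8% and 88.4% to 0.850% and 0.914%. These are shares of all reads of the insert, not means over barcodes.

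Among inserts past the threshold, those with an added splice donor gave less RNA per DNA than their controls, and those with a mutated donor mostly more. Every added donor past the threshold lowered RNA per DNA, 12 of 20 inserts in the episomal and 4 of 20 in the lentiviral vector. The 4 that passed in both were ZNF254, a zinc finger gene (-1.69 ± 0.18 and -0.88 ± 0.17), RAP1GAP, a GTPase activator (-1.12 ± 0.23 and -1.51 ± 0.28), DCUN1D4 (-0.99 ± 0.25 and -1.19 ± 0.30) and LSM8, an RNA-processing protein (-0.93 ± 0.24 and -0.60 ± 0.18). Mutating a donor raised 9 of 19 inserts and lowered 3 in the episomal vector, and raised 10 of 20 and lowered 1 in the lentiviral vector. ZDHHC4 rose by 1.41 ± 0.17 and 3.83 ± 0.22, ANAPC15, an anaphase-promoting complex subunit, by 1.60 ± 0.26 and 2.38 ± 0.39, and MAPK8IP3 by 0.93 ± 0.24 and 1.80 ± 0.26. The site on chromosome 8 at 144691691 was lowered in both (-1.48 ± 0.19 and -0.94 ± 0.17). The effects differed between the vectors for 5 of 20 added and 6 of 19 mutated donors, with the largest differences at the chromosome 7 site at 96358277 (2.01 ± 0.21) and at ZDHHC4 (2.42 ± 0.19). The real split of the barcodes gave the largest profile distance of 35 splits in 14 of 20 added and 14 of 17 mutated inserts in the episomal vector and in 15 of 20 and 15 of 19 in the lentiviral vector. Chance would give under 1 in each set, and for single-base alleles the real split gave the largest distance in 10 of 42 and 11 of 43 pairs. The main start moved by over 5 bp in 4 of 20 and 8 of 17, and in 9 of 20 and 12 of 19. Among single-base alleles it moved as far in 9 of 42 episomal and 10 of 43 lentiviral pairs. The share for episomal added donors was thus near that of the alleles. Outside the episomal added donors the directions of RNA per DNA rest on the division by DNA reads. Without it 0 added donors were raised and 3 lowered in the episomal vector, and 2 raised and 1 lowered in the lentiviral vector. Of mutated donors 2 were raised and 3 lowered in the episomal vector, and 3 raised and 3 lowered in the lentiviral vector.

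**Figure D4:**
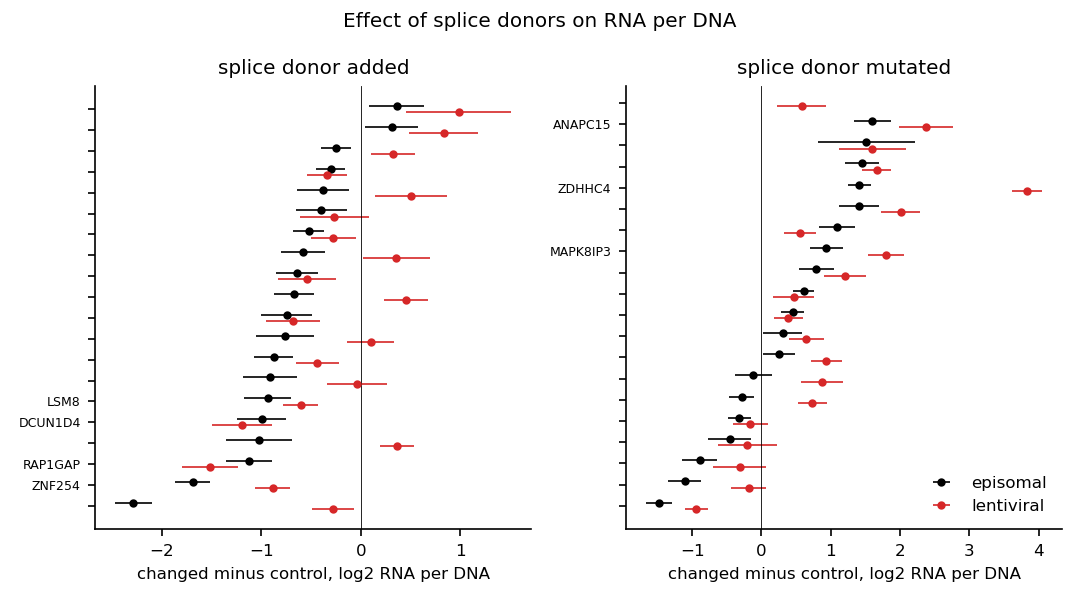
Log2 RNA per DNA of inserts with an added or mutated splice donor minus their controls, in the episomal and lentiviral vectors, as points with SE bars from limma over 2 to 4 barcodes per insert; genes named in the paragraph above are labelled. Every added donor past the threshold lies below 0, and among mutated donors ZDHHC4 reaches 1.41 and 3.83.

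Of the single-base alleles tested 10 of 44 passed in the episomal vector, 4 raised and 6 lowered, and 11 of 45 in the lentiviral vector, 6 raised and 5 lowered. The 6 that passed in both had the same sign, among them the allele insert at DDX5, an RNA helicase gene (1.04 ± 0.17 and 1.02 ± 0.24), the insert opposite MAPK3 (0.99 ± 0.18 and 0.80 ± 0.20) and a site on chromosome 1 from 6609765 (-1.04 ± 0.28 and -1.82 ± 0.24). The effects differed between the vectors for 3 of 44, at TNPO1, a nuclear import receptor (-0.01 ± 0.15 and 1.36 ± 0.25), at NFRKB (-0.74 ± 0.40 and -1.91 ± 0.67) and opposite PGP (0.30 ± 0.24 and 1.43 ± 0.31). Without division by DNA reads 1 allele passed in the episomal and 5 in the lentiviral vector.

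The next question was whether the vector moves the start site within an insert. The highest start kept its place in most inserts while the weaker starts around it differed. The median earth mover distance between profiles of short inserts was 3.44 bp between the vectors, against 0.821 bp between episomal and 0.976 bp between lentiviral replicates, and it exceeded both replicate distances in 448 of 488 inserts. The highest position lay within 5 bp in 81.0% of short inserts between vectors, against 91.0% and 92.4% between replicates. For long inserts the distances were 7.50 bp between vectors against 3.18 and 1.75 bp, and 216 of 242 exceeded both; 75.3% had the highest position within 5 bp, against 89.0% and 91.8%. With each profile thinned to 50 reads the contrast was smaller, 5.27 bp between vectors against 3.77 and 3.58 bp for short and 10.11 bp against 7.28 and 6.08 bp for long inserts. PTMA, the prothymosin alpha promoter, had nearly the same profile in both vectors (0.391 bp), as did RPLP1 (0.506 bp), its NRF1 mutant (0.474 bp), the site opposite AFF1 (0.594 bp) and an intergenic site on chromosome 20 (from 2525706, 0.458 bp). Those that differed most were both allele inserts of an intronic site on chromosome X (from 40266637, 20.8 and 19.5 bp), the Meis1 mutant of HBE1-HS4neg (19.0 bp), an NEK11 intron whose main start lay at 147 in the episomal and 104 in the lentiviral vector (17.3 bp) and the Gata1 mutant of NPRL3-enh3neg (16.5 bp). Among long inserts ADK, TRIM21, WDR74, ELF1 and LINC03011 differed least (0.706, 0.739, 1.36, 1.46 and 1.80 bp), and introns of SYNJ2 (30.8 bp), FPR1 (24.8 bp) and CASS4 (23.2 bp), a site on chromosome 3 (27.1 bp) and the SOD2 promoter (23.5 bp) differed most.

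By the mean share of reads at the main start of random sites, starts were more focused in the lentiviral vector. This share was 27.5% and 27.3% in the EpiShort replicates against 33.1% and 33.1% in LentiShort. In long inserts it was 21.2% and 21.5% in EpiLong against 27.8% and 27.5% in LentiLong. A start at a pyrimidine followed by a purine, the core of the initiator, took 59.4% and 58.4% of reads in the EpiShort replicates and 66.3% and 66.5% in LentiShort, and 56.1% in both EpiLong replicates against 64.5% and 64.3% in LentiLong, means over random sites. The median random site used 85 and 84 positions in EpiShort against 54 and 55 in LentiShort, and 153 and 163 in EpiLong against 91 and 89 in LentiLong, counts that grow with reads. The main start lay within 5 bp of the site for which the insert was named in 53.5% to 57.0% of short and 34.8% to 38.4% of long inserts.

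The last comparison set the short against the long insert of the same random site. Some long inserts gave far less RNA than the short insert of the same site and others far more, with starts at all positions counted. The long insert of HNRNPA3, an RNA-binding protein gene (chromosome 2, 177212592 to 177212941), gave less RNA than the short one by -8.97 ± 0.17 in the episomal and -10.55 ± 0.19 in the lentiviral vector, and PCGF5 (chromosome 10, 91220581 to 91220930) by -7.02 ± 0.20 and -9.99 ± 0.21. Per DNA these were -8.69, -10.43, -4.96 and -9.01. GORASP1 differed by -3.97 ± 0.13 and -7.06 ± 0.10, NRBP2 by -7.14 ± 0.21 and -9.41 ± 0.14, and the site opposite TK2, a mitochondrial thymidine kinase, by -3.97 ± 0.26 and -7.95 ± 0.21. Per DNA they differed by -3.58 and -6.89, -2.84 and -6.97, and -3.12 and -7.52. The long insert of RNFT2 (chromosome 12, 116759762 to 116760111) gave more by 7.25 ± 0.22 and 7.37 ± 0.09, of MIR223HG, host of a myeloid microRNA (chromosome X, 66015149 to 66015498), by 7.16 ± 0.19 and 5.55 ± 0.14, and of the site opposite ABT1 by 5.47 ± 0.12 and 3.45 ± 0.08. Per DNA these gave more by 4.64 and 6.53, 5.59 and 4.48, and 5.42 and 2.69. Each of these passed in RNA and per DNA in both vectors, and their names were chosen after their values were seen.

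In edgeR 231 of 250 sites differed between lengths in the episomal vector, 129 higher and 102 lower in the long insert, and 229 in the lentiviral vector, 114 higher and 115 lower. The median over sites was 0.41 in the episomal vector and moved to 0.06 under RLE normalization and 0.14 under library totals, and from 0.00 to -0.50 in the lentiviral vector under library totals. Per DNA 188 and 210 differed. On average 59.1% and 62.2% of the reads of a long insert (episomal replicates) started within the positions at which short inserts had reads. In the lentiviral replicates it was 64.8% and 64.4%. The RNA of a long insert thus also counts starts outside that window. Within that window, up to position 164 of the short insert, the median profile distance between lengths was 6.69 bp in the episomal and 7.13 bp in the lentiviral vector. These lay above the distances between replicates, which ran from 0.776 to 1.45 bp. Insert length and library preparation cannot be told apart, since each length had its own libraries.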

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

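The tests on the share of DNA reads, on all pairs with an added donor, on CCAAT and ETS inserts after GC content, and on splits of the barcodes were chosen only after the results were seen, as was the comparison of effects between vectors, which was made on the changed inserts. How the intervals of the DNA share, of the initiator gap and of the CCAAT and ETS inserts were weighed was also set after their results were seen.

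Effects of 21 designed changes differed between the vectors by at least 2-fold in a limma test of the difference, and each is given here as the lentiviral minus the episomal effect (log2). The AP-1 mutants of the beta-globin control elements gave 3.01 (HBE1-HS2pos) and 2.26 (HBE1-HS4pos), the NRF1 mutants 2.58 at antisense NPRL3 and 1.00 at SF3B1, and the NFY mutants -2.46 at HBE1-HS1neg and -1.86 at the HBE1 promoter. At ACTB the CDX4 mutant gave 1.98 and the TATA box mutant 1.96, mutations that may overlap, and at HBZ the TATA box mutant gave -1.10. The Elk1 mutants gave 1.82 at SF3B1 and 1.12 at ENO1, the Sp1 mutant of TERT 1.22 and the p63 mutant of NPRL3-enh3neg 1.41. Mutated donors gave 2.42 at ZDHHC4 and 1.02 at BSDC1, and added donors 2.01 at the chromosome 7 site, 1.39 at DCAF4 and 1.13 at C1D. The allele inserts gave 1.37 at TNPO1, 1.13 opposite PGP and -1.17 at NFRKB.

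More changed inserts passed under the real grouping of the barcodes than under any other split, in either vector. In the episomal vector 59 of 131 pairs passed, the highest count among the other splits of the barcodes was 0, and 1 of 35 splits, the real one, reached the count. In the lentiviral vector 56 of 136 pairs passed, the highest other count was 1, and again 1 of 35 splits reached it. Every other split mixes changed and control barcodes, which adds any real difference to the spread, and 1 of 35 is the lowest share possible. The splits therefore cannot tell how many of the pairs passed by chance.

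Added splice donors lowered RNA per DNA in 12 of 20 inserts in the episomal and 4 of 20 in the lentiviral vector; without division by DNA reads 3 and 1 were lowered, and 2 raised in the lentiviral vector. Loss of the read part by splicing of transcripts that start upstream of the donor is a candidate explanation, under which starts downstream of the donor should fall less. Over 16 lowered pairs, 4 inserts counted in both vectors, the median downstream minus upstream change was 0.52 (95% interval -0.34 to 0.92, 10 positive). That met the size set in advance, which named no interval. Since the interval spans both signs, the explanation stays open. Over all 38 pairs the median change was 0.78 (0.06 to 1.13, 26 positive), and over the 22 that were not lowered 0.86 (0.19 to 1.35), so that the shift was not particular to lowered pairs. A donor consensus in the downstream part that long inserts alone hold went with a difference of -0.40 (-5.38 to 1.57, 5 inserts), too few to decide. An effect of the donor on transcription itself was not tested.

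RNA per DNA differed between the vectors for most inserts, and GC content met the size set for it in advance: its correlation with the difference was -0.521 across 335 short inserts with the edgeR values (-0.602 to -0.441). The DNA share correlated at -0.244 (-0.351 to -0.128), partly built in because the ratio holds the DNA reads. For CCAAT inserts the difference was 1.11 before and 0.82 after a quadratic fit on GC content (0.28 to 1.18, adjusted p = 0.00091, permutation test). A GC trend of that form did not take up the whole difference, but other forms of base composition were not fitted. The rule first used left CCAAT inserts undecided and was changed after the result was seen, so GC content is not excluded. For ETS inserts it was not decided either, at -1.0 before and -0.57 after (-1.22 to -0.03), which no longer passed (adjusted p = 0.179). A bias of amplification or packaging by GC content could therefore account for part of the vector difference, and an effect of the vector on GC-rich promoters stays open and untested.

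Starts fell on a pyrimidine followed by a purine less often in the episomal vector, in 58.9% against 66.3% of reads over 245 short random sites. Background reads are a candidate explanation and should weigh most on weak inserts. The gap was 5.04 percentage points in the 62 most active inserts and 11.7 in the 62 least active, so that the most active kept 67.9 percent of the gap of 7.42 (43.8 to 89.2), which does not decide between background and a looser choice of start sites. The latter was not tested.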

How the results depend on the processing

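The scalings by RLE, library totals and DESeq2, RNA per DNA, RNA not divided by DNA, thinned profiles, regression on GC content, the block for insert lengths and all alternatives for changed inserts were chosen only after the data were seen. The 44 inserts named for the size of their difference or as erythroid promoters kept direction and threshold under every scaling, filter, trend and block setting tried, and the counts of the vector and length comparisons stayed within 1.5 times: 422 to 452 for short inserts, 164 to 213 for long inserts, 215 to 239 for lengths in the episomal and 216 to 235 in the lentiviral vector, outside RNA per DNA. Of the other list members RPLP1 (-0.98 to 0.39), RPS26 (-0.85 to 1.24), JUN, DUSP1 and the short NDUFC1 insert took either sign over the scalings. Of the 20 named long inserts 1 no longer passed in the core table. Replicate numbers do not pair samples (correlation of replicate deviations between vectors -0.055 and -0.015); with the number as a block the counts were 442 and 185 for the vectors and 228 and 228 for lengths, and same-numbered pairs gave profile distances of 3.43 and 7.44 bp with 80.9% and 75.1% of highest positions nearby. Leaving out 1 replicate assumes that the lone sample varies like the other group. Pseudocounts of 0.1 and 5 for the vector tests were not run, since counts need none. The small DNA library of EpiShort replicate 2 and the 0 to 3 DNA reads of some inserts limit what RNA per DNA can show.

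With RNA per DNA 34 of 43 of the first group were unchanged, 6 no longer passed and 3 changed sign. The chromosome 5 exon (-0.83) and the long chromosome 6 site at 35731814 (-0.64) turned because their DNA shares differed. The IL18RAP allele insert (-0.56, adjusted p 1.00) had 0 episomal RNA and DNA reads, so that its ratio is not defined and shows no reversal. With RNA not divided by DNA, counts of changed inserts were 13 (motif), 1 (allele), 3 (donor added) and 5 (donor mutated) in the episomal vector, and 5 alleles and 6 mutated donors in the lentiviral vector. Mutated donors went from 9 raised and 3 lowered to 2 and 3 in the episomal and from 10 and 1 to 3 and 3 in the lentiviral vector, and lentiviral added donors from 0 raised and 4 lowered to 2 and 1. Of 73 single pairs 42 passed as before, 27 did not and 4 turned: Meis1 mutants of HBE1-HS4pos (0.19) and SF3B1 (-0.067) in the episomal vector, and CTCF (0.88) and NRF1 (0.29) mutants of HBQ in the lentiviral vector. The cause was not tested. Leaving out replicate 1 or 2 lost 2 and 1 of the 73, and at least 100 DNA reads or a pseudocount of 0.1 none of those tested.

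With GC content regressed out, the elements that passed in short inserts numbered 0 for RNA, 1 for RNA per DNA and 0 for episomal activity, and in long inserts 0, 0 for RNA per DNA and 0 for lentiviral activity. Of 22 single elements 1 was unchanged, 16 no longer passed and 5 turned: the GC box for RNA per DNA in short (0.27) and long inserts (0.042), for long RNA (0.13) and long lentiviral activity (0.82), and GATA in long inserts (-0.045), which the removal of the GC trend itself brings. In the 100-bp window 2, 1 and 1 elements passed in long inserts for RNA per DNA, episomal and lentiviral activity, with fewer elements tested.

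The erythroid list gave an adjusted p of 0.324, and 0.0974 per DNA, with an estimated correlation. Pearson correlations between replicates were 0.999 in EpiShort and 0.996 in LentiLong at a mean of at least 50 counts, and 0.996 in LentiShort with no filter.

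For profiles, values follow for episomal replicates, lentiviral replicates and between vectors. Total variation was 0.0692, 0.0817 and 0.203 in short and 0.0921, 0.102 and 0.243 in long inserts. Thinned to 50 reads, distances were 3.77, 3.58 and 5.27 bp in short and 7.28, 6.08 and 10.11 bp in long inserts, and 75.4%, 79.9% and 72.7% of short and 69.9%, 67.6% and 64.6% of long inserts had highest positions nearby, since fewer reads scatter more. Within 1 bp the shares were 88.5%, 90.7% and 77.6% in short and 87.0%, 89.8% and 72.9% in long inserts. At a minimum of 200 counts the share was 92.4% for short episomal replicates and 77.1% for long inserts between vectors. In the core table distances were 1.501, 1.23 and 4.15 bp, with 91.2% (episomal replicates) and 80.5% (between vectors) nearby, from a narrower window. Leaving out each replicate gave 3.33 to 3.44 bp for short inserts between vectors.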

Other observations

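The tests of changed inserts given here were chosen only after the data were seen, and no further hypothesis was tested.

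Some motif mutations raised the RNA per DNA of their insert. The RUNX-AML mutant of ENO1, the glycolytic enolase promoter, rose in both vectors (1.16 ± 0.23 episomal, 1.22 ± 0.42 lentiviral), while its PU.1 mutant, which loses an ETS-type site, fell in both (-1.11 ± 0.20 and -0.97 ± 0.24). The p63 mutant of the enhancer NPRL3-enh3neg rose in both vectors (0.95 ± 0.31 and 2.62 ± 0.53). The CTCF and p63 mutants of NPRL3-enh3pos rose in the lentiviral vector (1.63 ± 0.35 and 1.68 ± 0.39), with 0.54 ± 0.42 and 0.72 ± 0.43 in the episomal vector, and the vector difference passed for neither. At JUN the NFIL3 mutant fell in both (-0.63 ± 0.18 and -0.78 ± 0.25), and the CRE mutant fell in the episomal vector (-1.18 ± 0.21) and gave -0.31 ± 0.18 in the lentiviral one, a difference of 0.87 ± 0.21. These inserts were chosen after their values were seen.

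Inserts in the alpha-globin and beta-globin regions that could be measured in the lentiviral vector alone also lost RNA per DNA when motifs were mutated. The CTCF mutant of HBE1-HS5neg fell by 3.67 (SE 0.58), and the CTCF and NRF1 mutants of HBQ, an alpha-like globin, fell by 1.56 (SE 0.25) and 1.94 (SE 0.36) per DNA, although the HBQ values turned positive when RNA was not divided by DNA. Start sites moved in the donor sets as well: at MAPK8IP3 mutation of the donor moved the main start from 128 to 158 in both vectors and at ANAPC15 from 117 to 149, and at DCUN1D4 the added donor moved it from 128 to 157.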
